A study of Macaca mulatta with 24 samples.

How the data were processed

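Total RNA from the thoracic aorta of 24 adult male rhesus monkeys was measured on 1 microarray per animal, a human expression BeadChip. The animals had eaten 1 of 3 diets for 24 months. Per the labels, 4 ate a standard diet, 10 ate a high-fat/high-sucrose diet, and 10 ate the high-fat/high-sucrose diet with resveratrol, a plant polyphenol, at 80 mg per day in year 1 and 240 mg per day in year 2. The standard diet had 13% of its energy as fat and the high-fat/high-sucrose diet had 42%. Per the labels, RNA was extracted with Trizol and a spin column, labelled with biotin and hybridised, and GenomeStudio 1.6.0 is named in the submitters' processing notes.

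The deposited table of raw values gives, per the file headers, an average probe intensity (unit: intensity, linear scale) for each of 47323 probes on each array. The lowest values lie well above 0 and the arrays have different medians, so these intensities are neither background-subtracted nor normalised between arrays. Beside each intensity, the deposited table gives a detection p-value, which compares a probe with the negative control beads of its array. No probe had a value missing on some arrays only, and 92 probes had no value on any array. The deposited series matrix holds a score, a z-score per array: each array's score was an exact linear function of the log2 of its raw intensity, with a slope equal to 1 over the SD of all its probes. It covers 23122 probes; 20066 of these reached a detection p-value under 0.02 on some array, and 0 of the probes left out did. The files name no array slide, hybridisation day or RNA quality, so batches could not be looked for, and no probe coordinates on the rhesus genome were used. The probes were designed on human sequence, and their match to rhesus transcripts was not checked.

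The raw intensities were background-corrected and normalised with neqc of limma 3.58.1 under R 4.3.3. Negative control values were inferred from the detection p-values, an offset of 16 was added, arrays were quantile-normalised, and values were taken to log2. A probe was tested when its detection p-value was under 0.05 on at least 4 of the 24 arrays, which left 17028 probes. Of these, 12211 had 1 gene symbol in the probe table, 1 had several and 4816 had none. For gene values, the probe with the highest mean over the 24 arrays stood for its gene, which gave 9939 genes, of which 9159 have a symbol that is also in the rhesus gene tables. The number of detected probes per array is given in the report as the depth. The number of arrays, above all the 4 of the standard diet, limits the precision.

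A single limma model with the 3 groups was fitted to all 24 arrays, with moderated tests, and 3 contrasts were read from it: the high-fat/high-sucrose diet minus the standard diet, resveratrol minus no resveratrol on the high-fat/high-sucrose diet, and the high-fat/high-sucrose diet with resveratrol minus the standard diet. All tests are two-sided. P-values were adjusted by the Benjamini-Hochberg method over the probes tested, with a threshold of 0.05. Gene lists were written from general knowledge of the artery wall, of metabolism and of stress responses. Of 46 lists, the 43 with at least 5 tested genes were compared with all other genes by camera, with a preset correlation of 0.01 between the genes of a list, and adjusted over the lists. The lists of T and NK cell, nerve and lymphatic markers had fewer tested genes. Camera with an estimated correlation, fry (which tests whether a list's genes move, on balance, 1 way) and a permutation of the list means between animals were run beside it. The list mean of an animal, called its score, is the mean over members of the log2 value minus that gene's mean over the 24 arrays. Permutation tests against the 4 standard-diet animals were exact, over all allocations, and those of 10 against 10 used 100000 permutations.

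The genes named were chosen by a rule. Where fewer than 10 genes passed the threshold in a comparison, the 10 with the smallest p are named and said not to pass. For each list that passed, and for 8 lists reported in any case, the 4 members with the smallest p are named. The 8 lists are contractile smooth muscle, elastic fibre and microfibril, fibrillar and other collagens, NF-kB and vascular inflammation, macrophage markers, endothelial markers, white adipocyte markers, and mitochondrial biogenesis and sirtuins. SIRT1, PRKAA1, NOS3, ELN, ACTA2, MYH11, VCAM1 and CCL2 were to be named in any case; SIRT1 and CCL2 were not detected on enough arrays to be tested. The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. No change is given for a named gene detected on at most 50% of the arrays in both groups compared, a rule added after the data were seen; the report gives its detection. Where only 1 of the 2 groups detected a gene on at most 50% of its arrays, the change is a difference from values near background, and its size is not exact. A count of animals showing a direction is the number of a group's arrays on that side of the mean of the group it is compared with.

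The alternatives were the deposited scores brought to the log2 scale, per-array z-scores of all probes, scaling by the array median, quantile normalisation without background correction, normexp background correction on the probe intensities alone with an offset of 50, no detection filter, detection p under 0.01 in at least 4 arrays, detection on all 24 arrays, the mean of all probes of a gene, only the 2 groups compared, array weights, a trend and robust setting of the moderated spread, the replicate number as a replicate block, an adjusted p under 0.10, and each array left out in turn. A few alternatives were chosen after seeing the data, namely leaving out the 3 arrays with a median correlation under 0.9 with the others, the mean of the white adipocyte markers as a covariate, the permutation of list means, and the lists under median scaling. The same steps were tested on simulated data, drawn from normal distributions with each probe's mean and SD, with known changes added to 200 of the 17028 probes.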

Results

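Gene expression was measured in the thoracic aorta of 24 adult male rhesus monkeys after 24 months on 3 diets, and each animal gave 1 array. There were 4 animals on a standard diet, 10 on a high-fat/high-sucrose diet and 10 on the high-fat/high-sucrose diet with daily resveratrol, a plant polyphenol. An array detected 13195.8 ± 1403 probes (SD, n = 4; range 11330 to 14368) in the standard-diet group at a detection p under 0.05. The numbers were 12447.8 ± 1322 (SD, n = 10; range 10326 to 14456) in the high-fat/high-sucrose group and 12239.1 ± 1738 (SD, n = 10; range 7933 to 13949) in the resveratrol group. Values below are normalised log2 intensities, as mean ± SD with 4 standard-diet, 10 high-fat/high-sucrose and 10 resveratrol animals. Changes are differences of log2 means with their standard error (SE) where given. The number of arrays limits the precision of every value. With the measured spread, a simulated change of 1 log2 unit was recovered for 50% of probes in the diet comparison, 80.5% in the resveratrol comparison and 57.5% in the comparison of resveratrol with the standard diet. A simulated change of 0.5 was recovered for 0%, 11.5% and 0%.

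The first comparison, the high-fat/high-sucrose diet against the standard diet, asks what 24 months of a diet rich in fat and sugar do to the artery wall. Genes of fuel oxidation in mitochondria were higher as a list, relative to all other genes. Of the list, 23 of 26 tested genes of the TCA cycle and fatty acid oxidation were higher, with a median log2 change of 0.27 (adjusted p = 0.0486 by camera, and adjusted p = 0.819 with an estimated correlation). Among them was SLC25A20, which carries acylcarnitines into mitochondria (6.80 ± 0.42 on the standard diet, 7.47 ± 1.06 on the high-fat/high-sucrose diet, change 0.67, SE 0.43). ETFDH of the electron transfer chain (0.59, SE 0.46), ACADM, which opens the oxidation of medium-chain fatty acids (0.54, SE 0.41), and citrate synthase CS (0.52, SE 0.38) were also higher. Without high-fat/high-sucrose replicate 7, an animal with strong fat tissue markers, these 4 were at 0.36, 0.22, 0.24 and 0.24. With all arrays, a second bright probe of CS was at 0.29 and a dim one at −0.0024. Heat shock genes, whose products refold damaged proteins, were lower as a list. In all, 12 of 16 were lower, with a median of −0.32 (adjusted p = 0.0486 by camera, and adjusted p = 0.747 with an estimated correlation). The co-chaperone DNAJB1 went from 8.06 ± 0.65 to 6.98 ± 0.54 (−1.08, SE 0.47). The small heat shock protein CRYAB went from 12.28 ± 0.36 to 11.62 ± 0.59 (−0.66, SE 0.30), and both were below the standard-diet mean in 10 of 10 animals. CRYAB stood apart as low in high-fat/high-sucrose replicate 7 (10.18, with the next animal at 11.25), so part of its change comes from that animal. DNAJA1 (−0.48, SE 0.23) and HSPA1B (−0.60, SE 0.33) were lower in 9 of 10 animals each.

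In the test of single probes, 0 of 17028 reached an adjusted p under 0.05 by limma in this comparison. The lowest adjusted p was 0.222, and 532 probes (216 higher, 316 lower) had an unadjusted p under 0.05, against 851.4 expected by chance. The 2 lists were those that passed of 43 tested. Camera with an estimated correlation, fry and the exact permutation of list means between animals called 0 lists each, where 14 lists had an unadjusted p under 0.05 by camera. For the oxidation list the mean per animal was above the standard-diet mean in 5 of 10 animals (exact permutation p = 0.70). For the heat shock list it was below in 9 of 10 (exact permutation p = 0.107). Without high-fat/high-sucrose replicate 7 the median of the oxidation list was −0.058 (adjusted p = 0.938), and that of the heat shock list was −0.18 (adjusted p = 0.0647). The oxidation call also ended without any 1 of standard-diet replicates 1 to 3, high-fat/high-sucrose replicate 10 and resveratrol replicates 4, 6, 8 and 10 (adjusted p 0.0512 to 0.234). The heat shock call ended without any 1 of standard-diet replicates 1 and 3, high-fat/high-sucrose replicates 1, 6 and 10 and the same resveratrol animals (adjusted p 0.0512 to 0.234). Scaling each array by its median moved the median of all probes by −0.28 in this comparison and turned the oxidation list to −0.17, which was 0.11 above that shift.

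**Figure D1:**
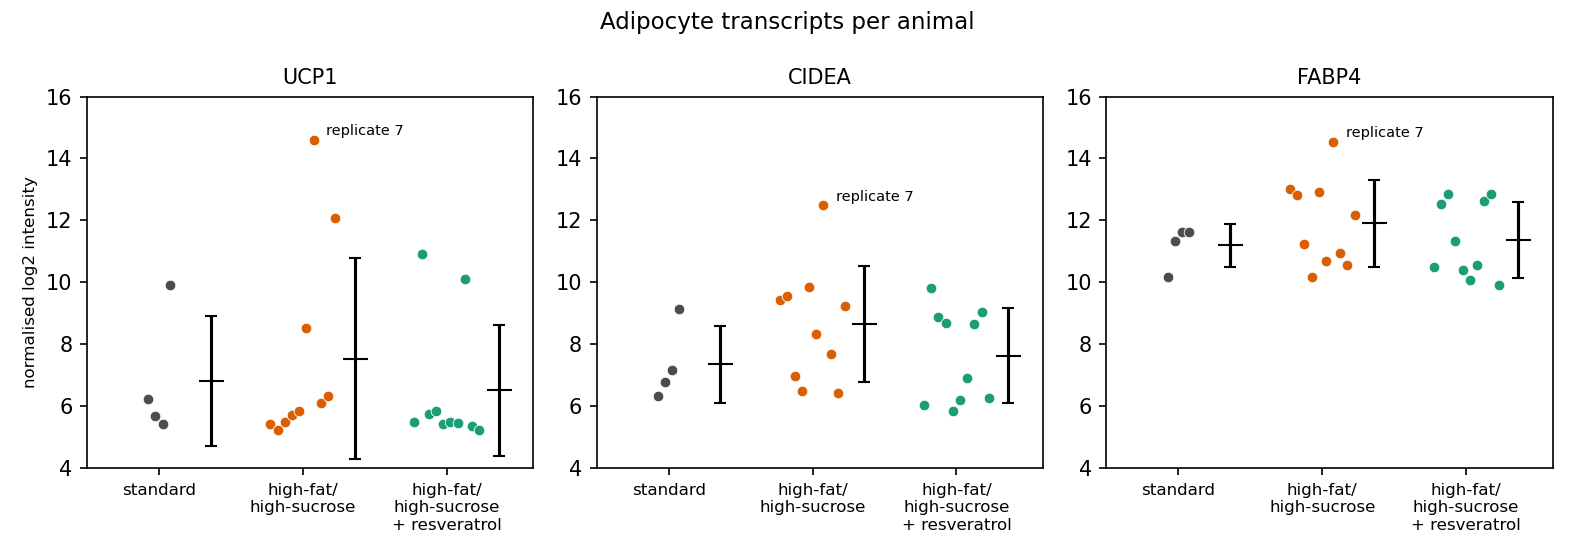
Log2 intensity of the brown fat gene UCP1 and of the fat cell genes CIDEA and FABP4 in each of the 24 animals by group, where points are animals and bars are group means ± SD. The genes were chosen after their values were seen; high-fat/high-sucrose replicate 7 stands at 14.61 for UCP1, while CIDEA and FABP4 are detected on 24 of 24 arrays.

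The genes with the smallest p did not pass the adjusted threshold. THOC2, of the complex that exports mRNA from the nucleus, was lower on the high-fat/high-sucrose diet in 9 of 10 animals (6.53 ± 0.39 against 5.45 ± 0.45, change −1.09, SE 0.22, adjusted p = 0.222 by limma). The scaffold gene USH1G was lower in 10 of 10 (6.53 ± 0.66 against 5.49 ± 0.30, change −1.04, SE 0.21, adjusted p = 0.222). MYH7, the slow myosin of heart and skeletal muscle, was at 7.23 ± 0.89 on the standard diet and 5.58 ± 0.46 on the high-fat/high-sucrose diet (−1.65, SE 0.36, adjusted p = 0.453, lower in 10 of 10). The growth factor receptor FGFR3 (−1.49), ACP4 (−1.01), the cytokine receptor IL21R (−0.81), ARMC6 (−0.72), the ephrin EFNA4 (−0.71) and the phospholipase PLA2G10 (−0.66) followed. All of these were near the detection limit, with 4 of 4 standard-diet arrays and 2 to 5 of 10 high-fat/high-sucrose arrays above it. ANXA2P2, an annexin A2 pseudogene, was higher in 10 of 10 animals (14.73 ± 0.31 against 15.19 ± 0.11, change 0.46, SE 0.13). Its probe was near the top of the intensity range, and whether it also reads annexin A2 itself was not checked.

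White adipocyte markers were higher for 14 of 15 genes (median 0.41, adjusted p = 0.0626 by camera), but the mean of the list was above the standard-diet mean in 5 of 10 animals. Among them were FABP4, the fatty acid carrier of fat cells (0.72, SE 0.69), and the lipase LIPE (0.81, SE 0.73), higher in 6 and 7 of 10 animals. Without high-fat/high-sucrose replicate 7 they were at 0.42 and 0.52, and the list median was 0.15. The lipases' partner PLIN1 and PCK1 were each detected on 1 of 4 standard-diet and 4 of 10 high-fat/high-sucrose arrays, so no change is given. Elastic fibre and microfibril genes were lower for 13 of 15 (median −0.24, adjusted p = 0.0917). The microfibril genes FBN1 and MFAP5 were at −0.38 and −0.63. LTBP1 was detected on 3 of 4 standard-diet and 1 of 10 high-fat/high-sucrose arrays, so the size of its change is not known. The cross-linking enzyme LOXL1 was detected on 1 of 4 and 4 of 10 arrays, so no change is given. Endothelial markers were higher for 10 of 11 (median 0.31, adjusted p = 0.169), with TEK at 0.59, ESAM at 0.30 and RAMP2 at 0.23. NOS3, the endothelial nitric oxide synthase, was detected on 2 of 4 standard-diet and 0 of 10 high-fat/high-sucrose arrays, so no change is given. NF-kB and vascular inflammation genes were higher for 8 of 12 (median 0.25, adjusted p = 0.251), with RELA at 0.51, NFKB1 at 0.28, CXCL8 at 0.27 (detected on 1 of 4 and 6 of 10 arrays) and CX3CL1 at −0.56. Macrophage markers were lower for 10 of 15 (median −0.16, adjusted p = 0.471), with MSR1 at −0.32 (detected on 3 of 4 and 4 of 10 arrays), VSIG4 at −0.30, AIF1 at −0.52 and CYBB at 0.29 (2 of 4 and 8 of 10). The 20 contractile smooth muscle genes had a median of −0.042 (adjusted p = 0.684), with MYL9 at −0.55, DES at −0.74 (detected on 3 of 4 and 3 of 10 arrays), ITGA8 at 0.64, ACTA2 at 0.27 and MYH11 at −0.16. With the deposited z-scores MYL9 was at 0.15, MYH11 at 0.54 and the list at 0.074, so their direction is not settled. For the 18 collagens, the median of −0.0095 and the mean of 0.022 differed in sign (camera direction up, adjusted p = 0.805), with COL6A2 at 0.51, COL6A1 at 0.39, COL4A1 at 0.19 and COL16A1 at −0.53. Mitochondrial biogenesis and sirtuin genes had a median of −0.081 (adjusted p = 0.656), with STK11 at −0.52 (detected on 3 of 4 and 2 of 10 arrays), SIRT5 at −0.18 and FOXO3 at −0.27. UCP2 was detected on 1 of 4 and 5 of 10 arrays, so no change is given. A less bright probe of SIRT5 was at 0.04. ELN was at −0.12 (SE 0.44), VCAM1 at 0.07 (SE 0.68) and PRKAA1 at 0.16 (SE 0.16). ELN turned to 0.08 and VCAM1 to −0.02 without high-fat/high-sucrose replicate 7, and MYH11 was at −0.06. The list medians without it were 0.12 for contractile genes and 0.14 for collagens, which turned, −0.13 for elastic fibre genes, 0.15 for NF-kB genes, 0.19 for endothelial markers and −0.13 for mitochondrial biogenesis genes. Without standard-diet replicate 2 the macrophage median turned to 0.037. Adjusted over the list alone, 0 members of these 8 lists and of the oxidation and heat shock lists passed.

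The second comparison asks whether resveratrol alters the artery wall of animals on the high-fat/high-sucrose diet. With resveratrol, genes of mitochondrial energy production were lower as a list. Of them, 43 of 46 nuclear genes of oxidative phosphorylation were lower, with a median log2 change of −0.32 (adjusted p = 1.15e-08 by camera). So were 25 of 26 genes of the TCA cycle and fatty acid oxidation (median −0.31, adjusted p = 6.37e-05). White adipocyte markers were lower for 14 of 15 genes (median −0.50, adjusted p = 1.40e-04). Elastic fibre and microfibril genes were higher for 14 of 15 (median 0.19, adjusted p = 0.00153). Immediate early genes, which respond within minutes to stimulation or stress, were higher for 16 of 22 (median 0.26, adjusted p = 0.00171). None of these calls held when the correlation was estimated (adjusted p = 0.714 with an estimated correlation for each list).

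**Figure D2:**
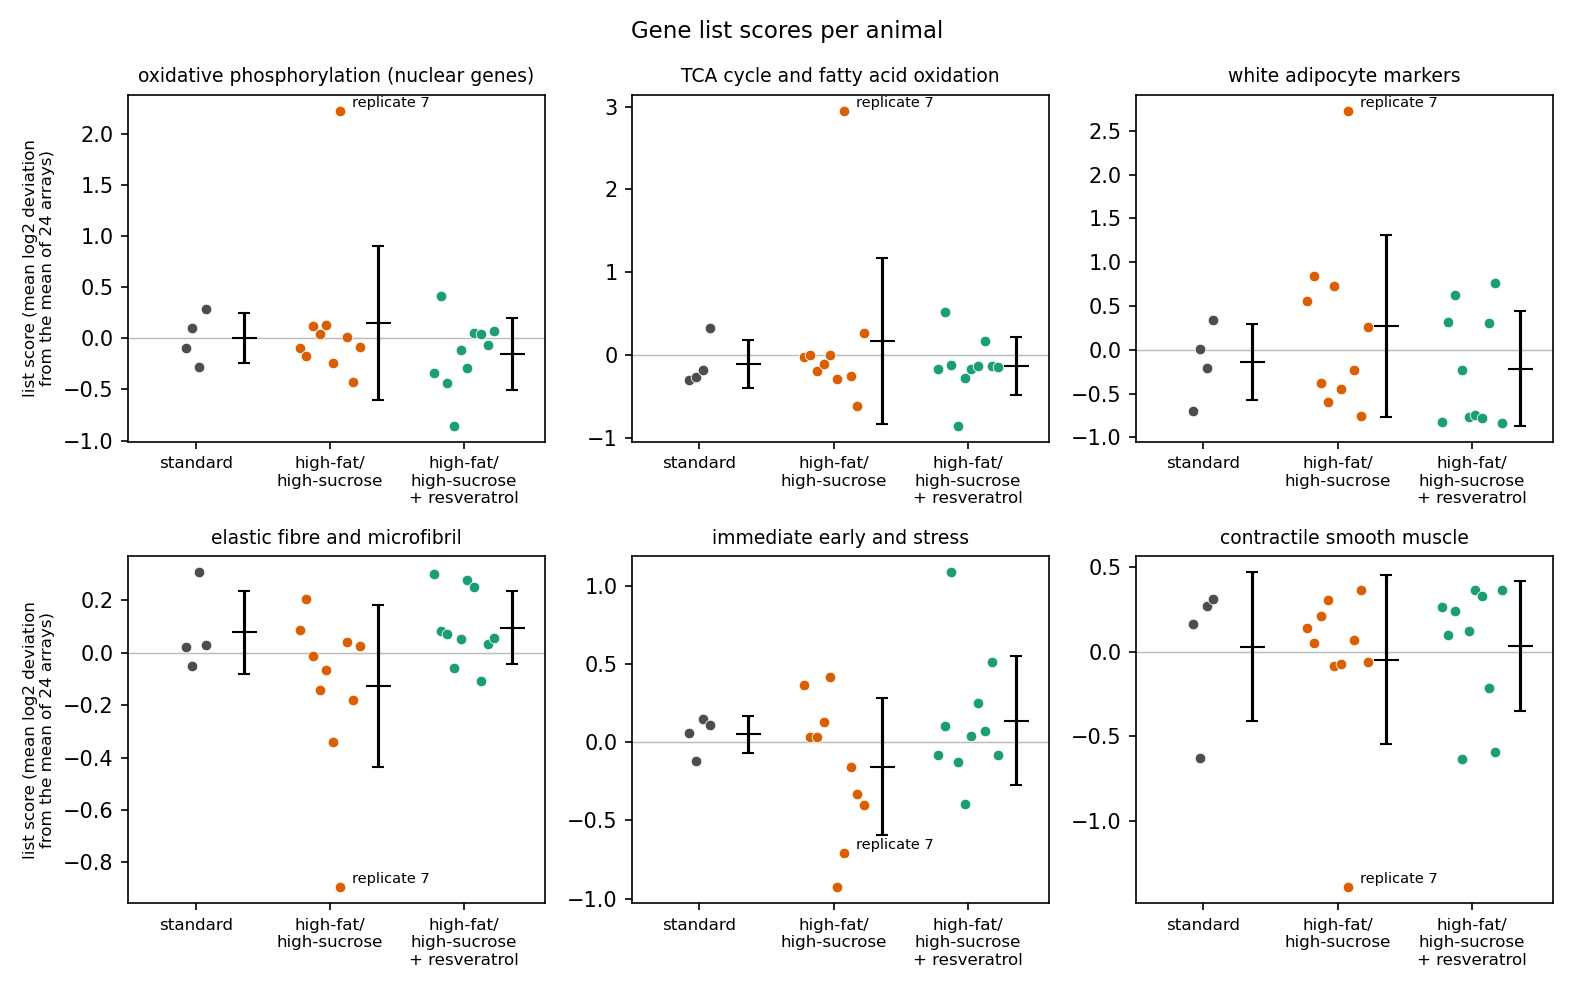
The mean of 6 gene lists in each animal, in log2 units relative to the mean of the 24 arrays, by group, where points are animals, bars are group means ± SD and each panel has its own axis. High-fat/high-sucrose replicate 7, marked, has a score of 2.23 for oxidative phosphorylation and 2.73 for white adipocyte markers, and −0.90 for elastic fibres.

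Among the members of these lists, the fibrillin gene FBN2, a microfibril component, was at 6.72 ± 0.63 without and 7.38 ± 0.27 with resveratrol (0.66, SE 0.20), above the other group's mean in 10 of 10 animals. It was the 1 member called when adjusted over the list alone (adjusted p = 0.0436 by limma), which does not allow for the other lists. Over all 17028 probes it did not pass (lowest adjusted p of any probe 0.999 by limma). The microfibril genes LTBP2 (0.39, SE 0.24) and FBN1 (0.29, SE 0.17) were higher in 7 and 8 of 10 animals. LTBP1 was detected on 1 of 10 arrays without and 3 of 10 with resveratrol, so no change is given. Lipoprotein lipase LPL, which releases fatty acids from blood lipids, was at 7.55 ± 1.85 without and 6.37 ± 1.14 with resveratrol (−1.18, SE 0.62). The lipid synthesis gene THRSP was also lower (−1.19, SE 0.69). No change is given for the lipid synthesis gene DGAT2 (detected on 3 of 10 and 1 of 10 arrays) and the droplet coat gene PLIN1 (4 of 10 and 3 of 10). Of the respiratory chain, NDUFB7 (−0.60, SE 0.29), NDUFA2 (−0.55, SE 0.32), SDHC (−0.39, SE 0.23) and NDUFV1 (−0.36, SE 0.22) were lower in 8 to 9 of 10 animals. Of fuel oxidation, ACAA2 (−0.62, SE 0.39), ETFB (−0.55, SE 0.39), ECHS1 (−0.53, SE 0.29) and SUCLG1 (−0.41, SE 0.29) were lower. The immediate early transcription factors EGR3 (0.99, SE 0.37), FOSB (0.89, SE 0.46) and FOS (0.53, SE 0.30) and the mRNA decay factor ZFP36 (0.58, SE 0.29) were higher, in 6, 7, 9 and 9 of 10 animals. EGR3 was detected on 2 of 10 arrays without and 6 of 10 with resveratrol, and its other tested probe, of similar brightness (5.64 against 5.80), was at −0.07.

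The counts of animals above are set against a mean that includes high-fat/high-sucrose replicate 7. Many of the changes were smaller without it. LPL was then at −0.70 and THRSP at −0.71, and LTBP2 at 0.24, FBN1 at 0.19 and FBN2 at 0.57. NDUFB7 was at −0.41, NDUFA2 at −0.28, SDHC at −0.15, NDUFV1 at −0.17, ACAA2 at −0.22, ETFB at −0.23, ECHS1 at −0.24 and SUCLG1 at −0.14. The immediate early genes moved less, with EGR3 at 0.95, FOSB at 0.75, FOS at 0.45 and ZFP36 at 0.50.

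A further 4 lists passed by camera, none of them with an estimated correlation (adjusted p = 0.714 with an estimated correlation for each). Cytosolic ribosomal protein genes were lower for 40 of 47 (median −0.099, adjusted p = 0.00135), with RPL14 at −1.04 (SE 0.41, detected on 6 of 10 arrays without and 2 of 10 with resveratrol), RPL35 at −0.50, RPL8 at −0.37 and RPS20 at −0.36. Genes of lipid transport and of the LXR and PPAR lipid sensors were lower for 19 of 22 (median −0.21, adjusted p = 0.00778), with CETP at −0.95 (SE 0.54, detected on 7 of 10 and 5 of 10 arrays), MYLIP at −0.32 and the lipoprotein receptor SCARB1 at −0.31. The lipid sensor NR1H3 was detected on 4 of 10 and 3 of 10 arrays, so no change is given. Heat shock genes were higher for 13 of 16 (median 0.19, adjusted p = 0.0176), with HSPH1 at 0.60 (SE 0.28), DNAJB1 at 0.53, HSPA1B at 0.49 and DNAJA1 at 0.46. Proteoglycan and adhesive matrix genes were higher for 14 of 17 (median 0.094, adjusted p = 0.0491), with VCAN at 0.46 (SE 0.24), THBS2 at 0.37 and NID1 at 0.31. FN1 was detected on 1 of 10 and 4 of 10 arrays, so no change is given. CETP was at −0.48, VCAN at 0.26 and THBS2 at 0.22 without high-fat/high-sucrose replicate 7.

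These calls compare genes within a list against other genes, while the animals themselves overlapped. By permutation of list means between animals, p was 0.302 for oxidative phosphorylation (−0.152 ± 0.348 with and 0.150 ± 0.749 without resveratrol, lower in 9 of 10). It was 0.507 for fuel oxidation (lower in 8 of 10), 0.234 for white adipocyte markers (lower in 6 of 10) and 0.142 for immediate early genes (higher in 9 of 10). The lowest p was 0.0311 for elastic fibre genes (0.0962 ± 0.138 against −0.127 ± 0.310, higher in 10 of 10; adjusted over 43 lists 0.924). The counts of animals are set against a high-fat/high-sucrose mean that includes replicate 7. Without it the difference of mean scores went from −0.302 to −0.071 for oxidative phosphorylation and from −0.305 to 0.0032 for fuel oxidation. It went from −0.485 to −0.212 for white adipocyte markers, from 0.223 to 0.138 for elastic fibre genes and from 0.293 to 0.231 for immediate early genes. Without high-fat/high-sucrose replicate 7 the medians were −0.049 for oxidative phosphorylation (adjusted p = 0.255), 0.00085 for fuel oxidation (0.946) and −0.20 for white adipocyte markers (0.111). They were 0.14 for elastic fibre genes (0.111), −0.15 for lipid transport (0.255) and 0.067 for proteoglycans (0.327). The other 3 lists passed without that animal, each at adjusted p = 0.0421, with medians of 0.14 for heat shock, 0.16 for immediate early and −0.083 for ribosomal genes. Without resveratrol replicate 3 immediate early genes had a median of 0.19 (adjusted p = 0.0896) and ribosomal genes of −0.050 (adjusted p = 0.0937). Without resveratrol replicate 4 the medians were −0.045 for ribosomal genes (adjusted p = 0.109), −0.12 for lipid transport genes (adjusted p = 0.0510) and 0.17 for proteoglycans (adjusted p = 0.109). The lipid transport call also ended without resveratrol replicate 7 or 10 (0.0701 and 0.0629), and the heat shock call without any 1 of high-fat/high-sucrose replicates 1, 6 and 10 and resveratrol replicates 2, 3 and 7 (0.0636 to 0.132). The proteoglycan call ended in 12 of the 24 cases in which 1 array was left out (0.0505 to 0.327).

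**Figure D3:**
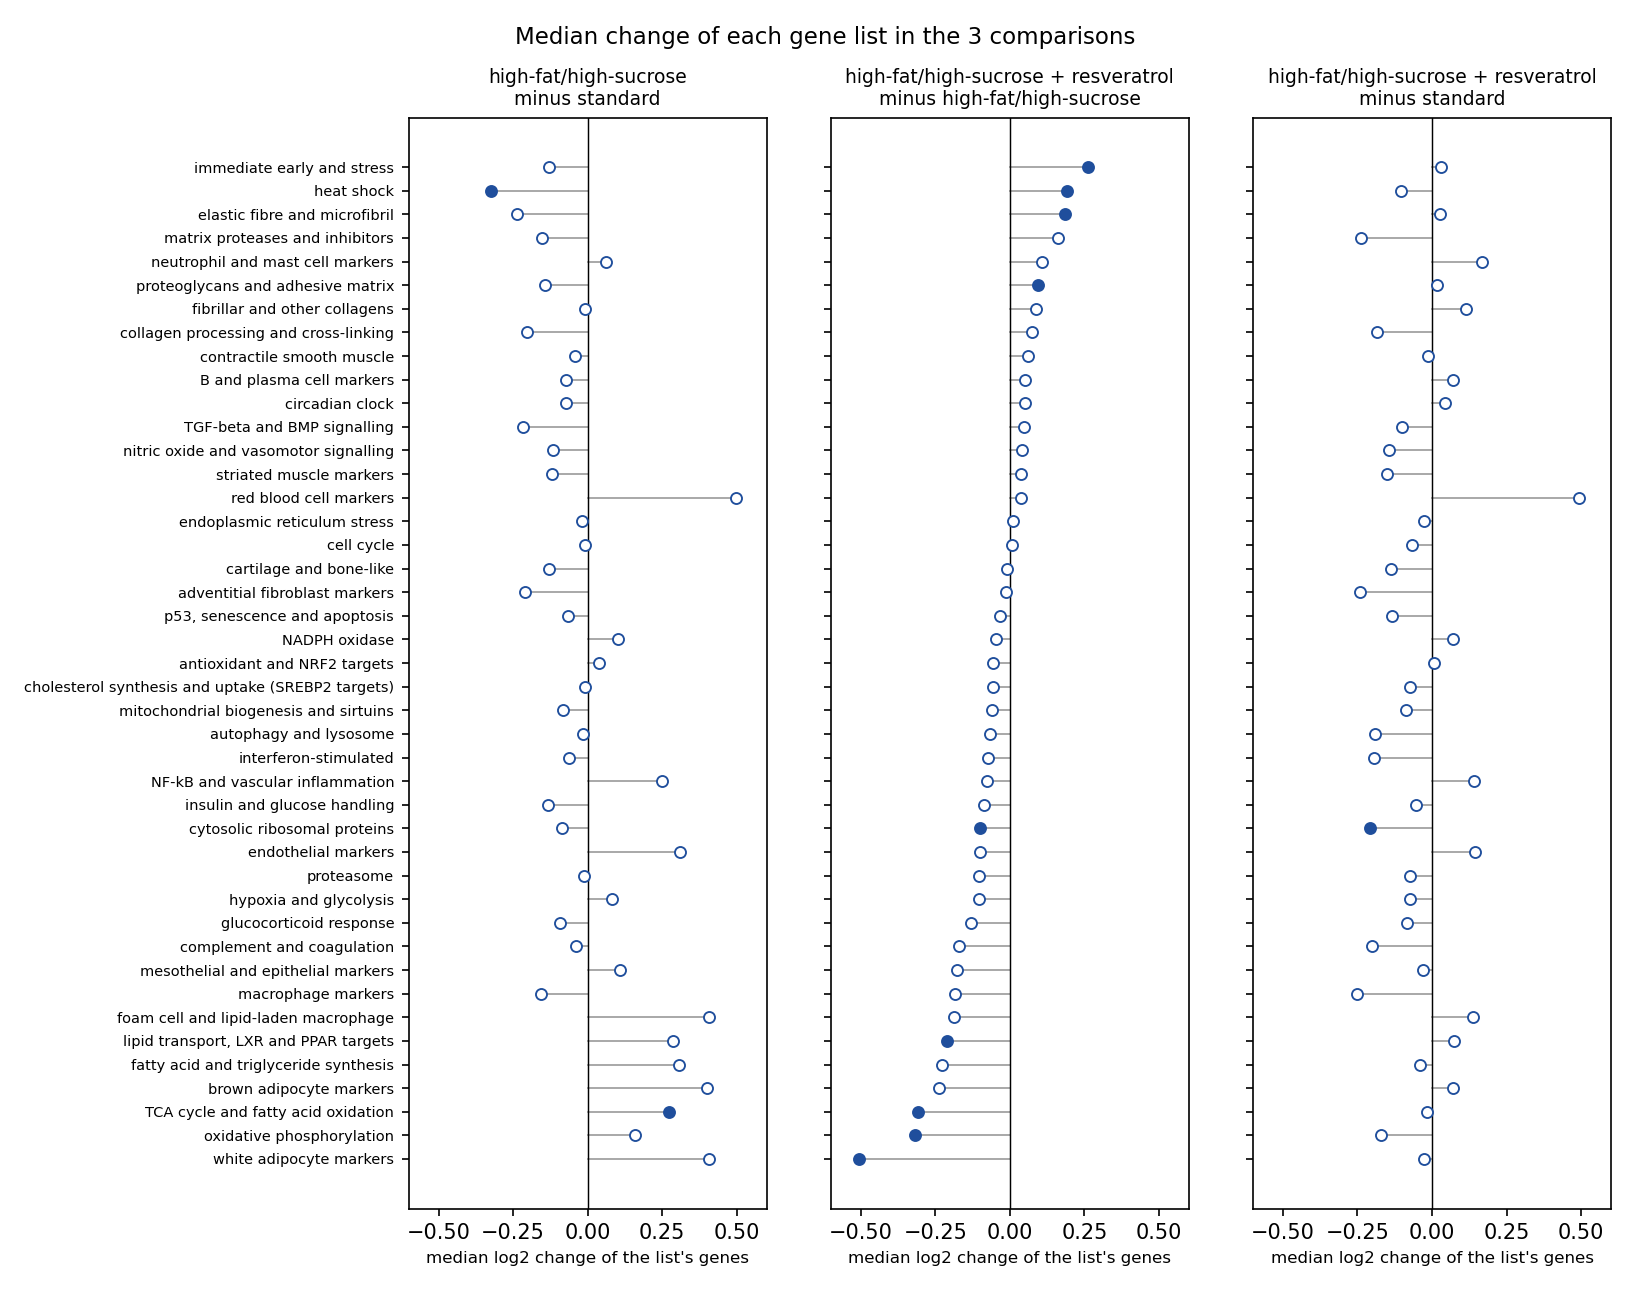
Median log2 change of the tested genes of 43 gene lists (one line each) in the 3 comparisons, with filled points where camera with a preset correlation gave an adjusted p under 0.05: 2 lists in the diet comparison, 9 in the resveratrol comparison and 1 in the comparison of resveratrol with the standard diet. None of the filled points held with an estimated correlation, and under median scaling the filled fuel oxidation point of the diet comparison turned to −0.17, which was 0.11 above the shift of all probes (−0.28).

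For single probes, limma called 0 of 17028 at an adjusted p under 0.05 (lowest 0.999), with 446 (261 higher, 185 lower) at an unadjusted p under 0.05. Camera called 9 of 43 lists, with 15 at an unadjusted p under 0.05; camera with an estimated correlation, fry and the permutation called 0. None of the 10 genes with the smallest p passed. The first were the small nucleolar RNA SNORA8 (5.74 ± 0.17 without and 6.38 ± 0.48 with resveratrol, change 0.64, SE 0.16, higher in 9 of 10) and UAP1L1 (−0.50, SE 0.14, lower in 10 of 10). The heat shock factor binding gene HSBP1 followed (7.89 ± 1.51 and 5.75 ± 1.06, change −2.14, SE 0.61, lower in 9 of 10, detected on 9 of 10 and 2 of 10 arrays), with the membrane protease ADAM9 (5.54 ± 0.32 and 6.54 ± 0.89, SE of the change 0.29, detected on 4 of 10 and 9 of 10). The others were RIOK1 (0.50), ROPN1L (0.35), FBN2, the translation release factor ETF1 (0.33), TOP2A, a topoisomerase of dividing cells (0.78), and PRRX1, a transcription factor of mesenchymal cells (0.59).

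Contractile genes were higher for 14 of 20 (median 0.062, adjusted p = 0.339 by camera), with MYLK at 0.46, TPM1 at 0.36, ACTG2 at 0.30, MYH11 at 0.21 and ACTA2 at −0.09. Collagens were higher for 13 of 18 (median 0.087, adjusted p = 0.463), with COL5A2 at 0.34, COL3A1 at 0.30 (a dim probe, mean log2 5.92), COL5A1 at 0.21 and COL8A2 at −0.31. Macrophage markers were lower for 12 of 15 (median −0.18, adjusted p = 0.0808), with CYBB at −0.29 and C1QA at −0.26. No change is given for TYROBP (detected on 2 of 10 and 2 of 10 arrays) and MSR1 (4 of 10 and 4 of 10). NF-kB and vascular inflammation genes had a median of −0.076 (adjusted p = 0.463), with CXCL8 at −0.35 (lower in 10 of 10, detected on 6 of 10 and 3 of 10 arrays), NFKB2 at −0.16, IL6 at 0.44 and PTGS2 at 0.39. Endothelial markers had a median of −0.099 (adjusted p = 0.463), with CLDN5 at −0.55, VWF at −0.24 and RAMP2 at −0.17. No change is given for NOS3, detected on 0 of 10 arrays without and 2 of 10 with resveratrol. Mitochondrial biogenesis and sirtuin genes had a median of −0.061 (adjusted p = 0.463), with TFB1M at −0.25, SIRT7 at −0.20 and FOXO3 at 0.25. UCP2 was detected on 5 of 10 and 2 of 10 arrays, so no change is given. ELN was at 0.33 (SE 0.33), VCAM1 at 0.17 (SE 0.51) and PRKAA1 at 0.07 (SE 0.12). The direction of IL6, VCAM1 and PRKAA1 turned with array weights, and that of ELN turned without the 3 arrays of low correlation. Without high-fat/high-sucrose replicate 7, MYLK was at 0.27, TPM1 at 0.16, ACTG2 at 0.12, MYH11 at 0.11, ACTA2 at −0.19, COL5A2 at 0.15, COL5A1 at 0.12, PTGS2 at 0.21, ELN at 0.14 and PRKAA1 at 0.04. The list medians without it were −0.063 for contractile genes, 0.028 for mitochondrial biogenesis genes and 3.1e-05 for NF-kB genes, which turned, 0.046 for collagens, −0.15 for macrophage markers and −0.017 for endothelial markers. The endothelial median also turned without high-fat/high-sucrose replicate 1 (0.015). A less bright probe of the gene had the opposite sign for TPM1 (−0.13), COL8A2 (0.10), NFKB2 (0.21), RAMP2 (0.20) and, among the genes with the smallest p, ETF1 (−0.06). Apart from FBN2, 0 members of these lists and of the 9 that passed were called when adjusted over the list alone.

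The third comparison sets the animals on the high-fat/high-sucrose diet with resveratrol against those on the standard diet. Since 0 of 17028 probes were called for the diet, it cannot show what of a diet effect is left under treatment. Cytosolic ribosomal protein genes were lower for 40 of 47, with a median log2 change of −0.21 (adjusted p = 8.52e-04 by camera, and adjusted p = 0.872 with an estimated correlation). RPL14 was at 6.78 ± 1.09 on the standard diet and 5.14 ± 0.70 with resveratrol (−1.64, SE 0.54; detected on 3 of 4 and 2 of 10 arrays). RPS15 (12.21 ± 0.32 against 11.76 ± 0.25, change −0.45, SE 0.18, lower in 10 of 10), RPL32 (−0.45, SE 0.23) and RPL5 (−0.44, SE 0.23) were also lower, while a dim second probe of RPL32 was at 0.28. The probes of RPL5 (mean log2 5.82) and RPL14 (5.85) were about as dim as that one (5.84), so the size of their changes is not exact. The mean of the list was below the standard-diet mean in 9 of 10 animals (exact permutation p = 0.231). Without standard-diet replicate 2 the median was −0.12 (adjusted p = 0.513), and with array weights it was −0.013 (adjusted p = 0.628).

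For single probes, limma called 0 of 17028 (lowest adjusted p 0.337), with 680 (326 higher, 354 lower) at an unadjusted p under 0.05. Camera called 1 of 43 lists, with 7 at an unadjusted p under 0.05, and the other list tests called 0. USH1G (−1.07, SE 0.21, adjusted p = 0.337 by limma) and THOC2 (6.53 ± 0.39 against 5.51 ± 0.26, change −1.03, SE 0.22, adjusted p = 0.337) had the smallest p again. Both were lower in 10 of 10 animals, against the same 4 standard-diet arrays as in the diet comparison. ARMC6 (−0.73), IL21R (−0.81), PLA2G10 (−0.69), ARHGAP32 (−0.94) and PDZD11 (−0.71) followed, and a second dim probe of PDZD11 was at 0.11. These 7 genes were detected on 3 to 4 of 4 standard-diet and 1 to 3 of 10 resveratrol arrays. RFPL4A and SERPINA11 were detected on 0 of 10 resveratrol arrays; taken against the detection limit they were at least 1.23-fold and at least 1.10-fold lower. CASTOR1, an arginine sensor of the mTORC1 growth pathway, was higher in 10 of 10 (6.18 ± 0.26 against 6.85 ± 0.26, change 0.67, SE 0.17, adjusted p = 0.671).

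Macrophage markers were lower for 12 of 15 genes (median −0.25, adjusted p = 0.199 by camera), with the complement genes C1QB at −1.03 (SE 0.70) and C1QA at −0.57 (SE 0.30), the growth factor receptor CSF1R at −0.69 (SE 0.41) and AIF1 at −0.60. Elastic fibre genes had a median of 0.028 (adjusted p = 0.847), with FBN2 at 0.33, FBLN5 at 0.20 (detected on 1 of 4 and 7 of 10 arrays) and LTBP1 at −0.21 (3 of 4 and 3 of 10). LOXL1 was detected on 1 of 4 and 3 of 10 arrays, so no change is given. White adipocyte markers had a median of −0.025 (adjusted p = 0.847), with LPL at −0.92 (SE 0.82) and CD36 at 0.35. No change is given for DGAT2 (detected on 1 of 4 and 1 of 10 arrays) and LGALS12 (2 of 4 and 4 of 10). Collagens were higher for 12 of 18 (median 0.12, adjusted p = 0.628), with COL3A1 at 0.40 (detected on 2 of 4 and 8 of 10 arrays), COL18A1 at 0.33, COL4A1 at 0.29 and COL8A2 at −0.38. Endothelial markers were higher for 9 of 11 (median 0.15, adjusted p = 0.628), with TEK at 0.49, PECAM1 at 0.34 and PLVAP at 0.21. NOS3 was detected on 2 of 4 and 2 of 10 arrays, so no change is given. NF-kB and vascular inflammation genes were higher for 8 of 12 (median 0.14, adjusted p = 0.751), with IL6 at 0.85 (SE 0.71), RELA at 0.44, CX3CL1 at −0.53 and NFKB2 at −0.31. For the contractile genes, the median of −0.013 and the mean of 0.0045 differed in sign (camera direction up, adjusted p = 0.847), with MYOCD, the master regulator of smooth muscle genes, at −0.75 (SE 0.40), MYL9 at −0.53, MYLK at 0.70, ACTA2 at 0.18 and MYH11 at 0.06. For MYL9 and MYLK a second bright probe had the opposite sign (0.25 and −0.10, mean log2 11.98 and 10.35), so their direction is not settled, and for MYOCD a less bright probe was at 0.28. Mitochondrial biogenesis and sirtuin genes were lower for 12 of 17 (median −0.089, adjusted p = 0.480), with STK11 at −0.50 (detected on 3 of 4 and 4 of 10 arrays), TFB1M at −0.34, FOXO1 at −0.28 and PRKAA1 at 0.23. ELN was at 0.22 (SE 0.44) and VCAM1 at 0.24 (SE 0.68). Adjusted over the list alone, 0 members of these lists and of the ribosomal list passed. Median scaling moved the median of all probes by −0.20 in this comparison. It turned the collagen median to −0.21 (−0.0074 with the shift taken off) and that of elastic fibre genes to −0.38 (−0.18 with it taken off), and with the deposited z-scores these medians were −0.016 and −0.058. The direction of both lists is therefore not settled, nor is that of the contractile genes (0.011 with the deposited z-scores), of white adipocyte markers (0.21 without standard-diet replicate 4) and of NF-kB genes (−0.029 without resveratrol replicate 9).

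Whether resveratrol moved genes back from where the diet had put them was asked by correlating the diet changes with the resveratrol changes across 9939 genes, which are not independent replicates. The Pearson correlation was −0.275, and 57.0% of genes had opposite signs. Both changes use the same 10 high-fat/high-sucrose arrays, which alone makes the correlation negative. Simulated groups with no change gave a mean of −0.379 (range −0.740 to 0.167), and 73 of 100 simulations were as low as the observed value. The covariance was −0.0137, against a simulated mean of −0.0266 (80 of 100 as low). When the 10 shared arrays were split 5 and 5 between the comparisons, the correlation had a mean of 0.153 over 100 splits (range −0.116 to 0.390), so the negative sign came from the shared arrays. A share of diet-called genes that moved back could not be given, since 0 genes were called by limma for the diet, with 316 genes at an unadjusted p under 0.05.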

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

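The 3 tests of the metabolic pattern in this part, and the alternatives that leave out arrays of low correlation or adjust for adipocyte markers, were chosen after the result was seen. In each group of 4 or 10 animals, the highest and lowest animal was checked for a large gap to the next animal (Dixon's test). The gap was read against the range of the group. This was done for each named gene, each array measure and a set of list scores. The set included brown adipocyte markers, TCA cycle and fatty acid oxidation, and oxidative phosphorylation. Chance picks about 1 in 20 groups; of 435 groups tested, 61 were picked, against 21.75 expected, and 49 of these were among 127 genes. Values are log2 intensities, or scores in log2 units where said.

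High-fat/high-sucrose replicate 7 gave most of them. Its scores were high for white adipocyte markers (2.73), brown adipocyte markers (2.96), TCA cycle and fatty acid oxidation (2.95) and oxidative phosphorylation (2.23), and low for contractile smooth muscle (−1.39), elastic fibres (−0.90) and collagens (−0.66). High genes were the white adipocyte markers PLIN1 (8.73), PCK1 (9.81) and DGAT2 (9.25), the lipid sensor NR1H3 (8.73) and UCP2 of the mitochondrial biogenesis list (7.95). The mitochondrial genes SLC25A20 (10.23), CS (13.28), ACADM (13.15), ETFDH (11.75), ECHS1 (12.17), ACAA2 (12.38), SUCLG1 (12.30), ETFB (12.17), NDUFB7 (10.63), NDUFA2 (11.76), NDUFV1 (10.68) and SDHC (11.12) were also high. Low genes were those of smooth muscle and its matrix, namely MYL9 (11.63), ACTA2 (13.88), ACTG2 (11.86), TPM1 (10.26), LTBP2 (10.76), VCAN (8.94) and THBS2 (8.63), and CRYAB (10.18) of the heat shock list.

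Cells of perivascular fat in this 1 array are a candidate source of the metabolic pattern of the resveratrol comparison. UCP1, the heat-producing uncoupler of brown fat, was at 14.61 in this animal and at 12.07 in the next, CIDEA was at 12.49, FABP4 at 14.54 and LPL at 11.85; LEP (9.72) was not raised, and ADIPOQ was dim on all 24 arrays (5.47 in this animal, 6.03 at the highest). Of the 15 white adipocyte markers, 8 were detected on all standard-diet arrays and 5 are also in another list, and no sort of cells would have removed fat. Without this animal the median of the oxidative phosphorylation list was −0.049 in place of −0.32 and the list no longer passed. So the pattern rests on this animal, but an animal picked for its high scores shrinks the change when left out, whatever the cause, and fat cannot be told apart from another cause by this test. Without resveratrol replicate 4, the array of lowest quality, the median was −0.21 in place of −0.32 and the list passed (adjusted p = 1.37e-05 by camera with the preset correlation). This argues against that array's quality as the whole cause, but a part of the change is not excluded. Without both this array and high-fat/high-sucrose replicate 7 the median was 0.0037 (adjusted p = 0.965 by camera). Whether resveratrol itself lowers these genes could not be told: without replicate 7 the list mean per animal differed by −0.071 (permutation p = 0.601), and a change in the amount of fat around the vessel, by treatment or by dissection, stays open and untested.

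Resveratrol replicate 4 had the fewest detected probes (7933) and the lowest median correlation with the other arrays (0.812). On it, COL5A1 (9.03), NID1 (7.31) and LGALS12 (6.53) were high, NDUFA2 (7.19), ETFB (7.01) and FOXO1 (5.50) were low, and the score of mitochondrial biogenesis and sirtuin genes was −0.52. In standard-diet replicate 2 the contractile score was low (−0.63), the collagen score was high (0.34) and the smooth muscle actin ACTG2 was low (12.66); it is also the animal without which the ribosomal list of the comparison of resveratrol with the standard diet did not pass.

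Single genes stood apart in other animals. In the high-fat/high-sucrose group, THOC2 (6.56), ACP4 (6.55) and NID1 (6.41) were high in replicate 2, SIRT5 (6.51) and HSPH1 (11.20) were high and RPS20 (5.83) was low in replicate 9, and ROPN1L (5.30) and RPS15 (11.06) were low in replicate 10. In the resveratrol group, PCK1 (6.74) and ROPN1L (6.62) were high in replicate 2, ACP4 (6.56) in replicate 3, LTBP1 (6.74) and HSBP1 (8.73) in replicate 9, and RPL14 (6.92) and PDZD11 (5.94) in replicate 10, while ANXA2P2 (14.75) was low in replicate 7 and FBN2 (6.74) in replicate 8. No cause was tested for these.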

How the results depend on the processing

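Alternatives that leave out arrays of low correlation, adjust for the adipocyte markers, permute list means or scale lists by the array median were chosen after the result was seen. The counts rest on few arrays, and those of lists also on high-fat/high-sucrose replicate 7, and dim probes limit the named genes, many of which lay near background. Changes kept their direction in every setting for 41 of 54 named genes in the diet comparison, 65 of 73 in the resveratrol comparison and 39 of 49 in the comparison of resveratrol with the standard diet, and, in the settings run for lists, for 6 of 10, 8 of 15 and 4 of 9 lists. The gene counts include turns under median scaling, which moves all probes; with that shift taken off, 48, 65 and 44 genes kept their direction. Median scaling was not among the settings of the lists, nor were normexp on probes, no detection filter, detection on all arrays and the mean of all probes. Read apart, median scaling turned 3 of 10, 2 of 15 and 4 of 9 list medians, and 0, 0 and 2 with the shift taken off (elastic fibre genes −0.18 and collagens −0.0074 against the standard diet). With 1 array left out, 4202 of 4224 gene values kept direction and side of the threshold, 19 turned and 3 passed. For lists 710 of 816 did, 47 no longer passed, 22 came to pass and 37 turned. Part of these counts was fixed in advance, because leaving out an array of the group outside a comparison cannot turn a change in it. No named gene passed with all arrays, so none could lose a call. Where a value below differs from the reported one, the cause was not tested, except that leaving out arrays or probes also changes what is tested. The array slide could not be used as a block, since the files give none. In what follows, counts and values are for the diet comparison, then the resveratrol comparison, then resveratrol against the standard diet.

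Probes called were 1, 1 and 14 with the deposited z-scores, 24, 1 and 54 with no detection filter, and 1, 0 and 1 without the 3 arrays of low correlation. Under median scaling they were 1, 0 and 4, and with only the 2 groups compared 0, 0 and 1. With 1 array left out they ranged from 0 to 1 (without standard diet replicate 4, for example) for the diet and for resveratrol against the standard diet. Lists called were 0, 0 and 0 by camera with estimated correlation, by fry and by permutation of list means. They were 0, 9 and 1 with the deposited z-scores, 0, 12 and 1 with per-array z-scores, 11, 10 and 1 at detection p under 0.01 in 4 arrays, and 1, 9 and 1 with only the 2 groups compared. They were 2, 12 and 0 with array weights, 1, 2 and 1 without the 3 arrays of low correlation, and 2, 1 and 1 with the adipocyte score as covariate. Leaving out 1 array gave 0 (high-fat/high-sucrose replicate 7, among others) to 15 lists (standard diet replicate 4), 3 (high-fat/high-sucrose replicate 7) to 17 (resveratrol replicate 9), and 0 (standard diet replicate 2) to 4 (standard diet replicate 1).

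With the replicate number as a replicate block, lists called were 0, 8 and 2, VCAM1 was at −0.12 for the diet, contractile genes were at 0.035 and collagens at 0.056 for the diet, and contractile genes were at 0.12 and NF-kB genes at −0.0061 for resveratrol against the standard diet.

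With the deposited z-scores and with per-array z-scores, for the diet, MYL9 was at 0.15, PRKAA1 at −0.021, MYH11 at 0.54 and contractile genes at 0.074. MYH11 was at −0.016 for resveratrol, and against the standard diet contractile genes were at 0.011, elastic fibre genes at −0.058 and collagens at −0.016; with the deposited z-scores alone NF-kB genes were at 0.018 for resveratrol and −0.0056 against the standard diet. Under median scaling, which moved the median of all probes by −0.28 for the diet, COL6A2 was at −0.042, COL6A1 at −0.17, COL4A1 at −0.31, NFKB1 at −0.28, ESAM at −0.24, RAMP2 at −0.12, CS at −0.041, ACADM at −0.012, PRKAA1 at −0.40 and VCAM1 at −0.13. Less the shift, COL4A1 (−0.022), PRKAA1 (−0.11) and MYH11 (0.032) were turned, and the others were not. For resveratrol RAMP2 was at 0.0052. Against the standard diet, with a shift of −0.20, FBN2 was at −0.043, COL4A1 at −0.17, COL18A1 at −0.15, PECAM1 at −0.11, PLVAP at −0.15, CD36 at −0.087, PRKAA1 at −0.24, ELN at −0.26 and MYH11 at −0.099. Less the shift, PRKAA1 (−0.036) and ELN (−0.064) were turned. With quantile normalisation without background correction, contractile genes were at 0.0042 against the standard diet, and with the mean of all tested probes NFKB2 was at 0.026 and RAMP2 at 0.014 for resveratrol.

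Without the 3 arrays of low correlation, for the diet, ELN was at 0.22, contractile genes at 0.10 and collagens at 0.099. For resveratrol RAMP2 was at 0.026, ELN at −0.088, NF-kB genes at 0.014, mitochondrial biogenesis genes at 0.018 and TCA cycle and fatty acid oxidation at 0.051. Against the standard diet contractile genes were at 0.16 and elastic fibre genes at −0.0096. With the adipocyte score as covariate, for the diet, ELN was at 0.091, VCAM1 at −0.32, contractile genes at 0.14, collagens at 0.11 and TCA cycle and fatty acid oxidation at −0.030. For resveratrol VWF was at 0.057, contractile genes at −0.11, NF-kB genes at 0.12, endothelial markers at 0.19, mitochondrial biogenesis genes at 0.0012, TCA cycle and fatty acid oxidation at 0.043 and lipid transport at 0.024, and against the standard diet white adipocyte markers were at 0.025. With array weights, collagens were at 0.14 and macrophage markers at 0.022 for the diet. For resveratrol IL6 was at −0.27, PRKAA1 at −0.040, VCAM1 at −0.14, collagens at −0.035 and mitochondrial biogenesis genes at 0.040, and contractile genes were at 0.052 against the standard diet. With the shared arrays split 5 and 5, the correlation of diet and resveratrol changes was 0.153.

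The ranges with 1 array left out, for results that turned in some of them, were as follows for the diet: ELN −0.48 to 0.078, MYH11 −0.35 to 0.043, VCAM1 −0.28 to 0.40, contractile genes −0.27 to 0.12, collagens −0.085 to 0.16, macrophage markers −0.30 to 0.037, and TCA cycle and fatty acid oxidation −0.058 to 0.39. For resveratrol they were VCAM1 −0.13 to 0.37, contractile genes −0.063 to 0.19, NF-kB genes −0.14 to 3.1e-05, endothelial markers −0.23 to 0.015, mitochondrial biogenesis genes −0.11 to 0.028, and TCA cycle and fatty acid oxidation −0.40 to 0.00085. For resveratrol against the standard diet they were CD36 −0.11 to 0.85, ELN −0.15 to 0.40, MYH11 −0.14 to 0.26, VCAM1 −0.11 to 0.57, contractile genes −0.20 to 0.16, elastic fibre genes −0.11 to 0.080, NF-kB genes −0.029 to 0.19, and white adipocyte markers −0.16 to 0.21.

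Lists that did not turn with 1 array left out also moved. For the diet their ranges were elastic fibre genes −0.29 to −0.13, NF-kB genes 0.11 to 0.29, endothelial markers 0.19 to 0.48, white adipocyte markers 0.15 to 0.59, mitochondrial biogenesis genes −0.13 to −0.027 and heat shock −0.48 to −0.18. For resveratrol they were elastic fibre genes 0.14 to 0.23, collagens 0.030 to 0.15, macrophage markers −0.28 to −0.097, white adipocyte markers −0.60 to −0.20, proteoglycans 0.067 to 0.20, oxidative phosphorylation −0.40 to −0.049, heat shock 0.13 to 0.22, immediate early genes 0.16 to 0.34, lipid transport −0.35 to −0.12 and ribosomal proteins −0.16 to −0.045. Against the standard diet they were collagens 0.059 to 0.20, macrophage markers −0.45 to −0.056, endothelial markers 0.0080 to 0.31, mitochondrial biogenesis genes −0.13 to −0.022 and ribosomal proteins −0.34 to −0.12.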

Other observations

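The relations with the adipocyte score, the held-out reading of the widely varying probes and the single genes of this part were chosen after the result was seen. Apart from high-fat/high-sucrose replicate 7, the brown fat gene UCP1 was at 12.07 in high-fat/high-sucrose replicate 10, 10.91 in resveratrol replicate 2, 10.10 in resveratrol replicate 8, 9.90 in standard-diet replicate 4 and 8.53 in high-fat/high-sucrose replicate 6, so UCP1 signal was present in all 3 groups. CIDEA was detected on 24 of 24 arrays (highest detection p 0.0143) and was high in animals in which UCP1 was low, namely at 9.86 in high-fat/high-sucrose replicate 5 (UCP1 5.85), 9.57 in replicate 2 (UCP1 5.24) and 9.44 in replicate 1 (UCP1 5.42). Across the 24 animals the score of white adipocyte markers was compared with 4 other list scores, which share 0 genes with it. It rose with fuel oxidation (Pearson r = 0.789, permutation p = 2.90e-04, adjusted 0.00116; Spearman 0.619, permutation p = 0.00161, adjusted 0.00468) and fell with contractile genes (r = −0.709, permutation p = 0.00117, adjusted 0.00234; Spearman −0.603, permutation p = 0.00234, adjusted 0.00468). Without the 2 farthest animals, high-fat/high-sucrose replicates 7 and 2, r was 0.486 and −0.452 (adjusted 0.0673 for each). Within the high-fat/high-sucrose group r was 0.903 and −0.894, and within the resveratrol group 0.324 and −0.557. The relation with oxidative phosphorylation (r = 0.687, permutation p = 0.00806, adjusted 0.0107; Spearman 0.277, permutation p = 0.186, adjusted 0.248; within groups 0.843 and 0.0779) rests on those animals, with r of 0.230 (adjusted 0.411) without them. For elastic fibres (r = −0.567, permutation p = 0.0180, adjusted 0.0180; Spearman −0.158, permutation p = 0.456, adjusted 0.456; within groups −0.537 and −0.552) r was −0.129 (adjusted 0.569) without them, although the resveratrol group holds neither of them.

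Some lists and members outside the naming rule also had low p-values without passing. TGF-beta and BMP signalling genes had a median of −0.22 for the diet (adjusted p = 0.0626 by camera) and −0.10 against the standard diet with resveratrol (adjusted p = 0.263; exact permutation p = 0.0160, adjusted 0.687; lower in 9 of 10). In the second of these, SMAD6, an inhibitor of BMP signalling, was called adjusted over the list alone (0.0310) at 9.06 ± 0.64 on the standard diet and 8.22 ± 0.32 with resveratrol. Interferon-stimulated genes were lower with resveratrol than on the standard diet in 10 of 10 animals (median −0.20, adjusted p = 0.263 by camera; exact permutation p = 0.0430, adjusted 0.924). Collagen processing genes had a median of −0.20 for the diet (adjusted p = 0.0917 by camera, lower in 8 of 10). Foam cell genes had medians of 0.41 for the diet (adjusted p = 0.0889) and −0.19 for resveratrol (adjusted p = 0.125), and brown adipocyte markers 0.40 (adjusted p = 0.0917) and −0.24 (adjusted p = 0.0808). Without high-fat/high-sucrose replicate 7 the 2 medians for resveratrol were −0.14 (adjusted p = 0.410) and −0.24 (adjusted p = 0.787), while the difference of the mean brown adipocyte scores went from −0.434 to −0.133. Without resveratrol replicate 4 the medians were −0.089 and −0.11. MYH7 in the striated muscle list (adjusted over the list alone 0.0012) was called this way for the diet. So were the heme synthesis gene ALAS2 (5.38 ± 0.11 on the standard diet, 5.88 ± 0.23 on the high-fat/high-sucrose diet, adjusted over its list 0.0115) and the cholesterol synthesis gene SC5D (6.01 ± 0.33 and 5.36 ± 0.25, adjusted over its list 0.0185). Both were dim, so the size of their changes is not exact. Against the standard diet FCGR3B of the neutrophil and mast cell list was called (7.00 ± 0.75 on the standard diet, 6.0 ± 0.52 with resveratrol, adjusted over its list 0.0363). Which cells its human probe reads in rhesus was not checked. Such calls do not allow for the other lists, and over all 17028 probes 0 passed by limma (lowest adjusted p 0.222 and 0.337). For striated muscle markers the exact permutation p for the diet was 0.0290 (adjusted 0.962) and 4 of 9 members were higher.

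With no detection filter, 24 of 47231 probes were called for the diet, all of them lower, with a median of 5.48 on the standard diet and 4.86 on the high-fat/high-sucrose diet (median change −0.61). Of these, 23 were detected on 3 arrays or fewer, and 24 were also lower with resveratrol against the same standard-diet arrays (20 called). The share of probes with an unadjusted p under 0.05 was 9.61% among probes detected on 0 to 3 arrays and 2.32% among those detected on 24. A greater number of detected probes on the standard-diet arrays as the whole cause is argued against, since 18 of the 24 were called with that number as a covariate. Chance is argued against for the count, since 1 of 100 splits gave as many, the real one, and the highest other gave 13. It is not excluded, because only 100 splits were drawn and the count belongs to 1 of several settings. Without background correction 8 of the 24 were called, so whether background correction makes the pattern could not be told; a batch of the standard-diet arrays or the diet itself could also be the cause, and the files cannot separate them. Leaving out 1 standard-diet array changed the count to between 18 and 85.

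A few probes varied widely over the 24 arrays, group differences included: 24 of the 12211 probes with 1 symbol (0.197%) had an SD of at least 1.5 log2 units. Among them were adipocyte markers (UCP1, CIDEA, THRSP, LPL and PPARG) and red blood cell markers (HBA1, HBA2 and HBB). Whether the share of fat or blood in the sample made these vary was not tested. HSBP1, named above for resveratrol, was also among them (SD 1.73, range 5.18 to 9.86). For other probes, sequence differences between animals under a human probe are a candidate cause, since they would silence 1 probe of a gene and leave another. For the 10 with another tested probe of their gene, the median ratio of the other probe's SD to theirs was 0.429; it was 0.112 for MGST1, 0.228 for SRP14, 0.289 for PPP2R3A, 0.346 for VEGFB, 0.417 for TPR and 0.441 for ITGB1, while HBA2 and PPARG varied in both (correlations 0.961 and 0.959). The test could not decide, since the probes were picked for their SD and the other probes of MGST1 (mean 5.45) and VEGFB (mean 5.57) lay near background, where they vary little in any case. In probes picked on 14 arrays and read on the other 10 the ratio was 0.614 (12 probes), and in those picked on 10 and read on 14 it was 0.291 (10 probes).

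The arrays were also split at random into groups of the same sizes. For probes, a real count of 0 in each of the 3 comparisons is reached by every split (100 of 100; the highest others called 10, 16 and 16), so these splits test nothing. For lists, chance could not be excluded: 93 of 100 splits gave as many as the real 2 of the diet comparison (highest other 22), 40 of 100 as many as the real 9 of the resveratrol comparison (highest other 19) and 92 of 100 as many as the real 1 against the standard diet (highest other 18). The other splits called a median of 8, 8 and 4 lists, so camera with the preset correlation commonly called lists in random groups too. With an estimated correlation it called 0 lists in the real groups. Why random splits call lists was not tested. Differences between animals that the groups do not explain, such as the share of fat tissue, are 1 candidate. The labels do not say whether the replicate numbers pair the animals, and the data showed no sign of it. Across the tested probes, the correlation between arrays of the same number had a median of −0.0909 between the high-fat/high-sucrose and resveratrol groups. Of 10 arrays, 1 correlated best with its own number.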
